A study of Arabidopsis thaliana with 434 samples.

How the data were processed

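NanoString nCounter counts were analysed for 67 probes in 434 leaf samples: 49 NAC genes, 4 reference genes (ACT2, ACT7, TUB2 and UBQ10), 8 negative and 6 positive control probes. Raw counts per probe were deposited as 4 tables, 1 per leaf age, and were used as they stand. Per the labels' protocols, total RNA was extracted from leaves and 100 ng entered each reaction with a custom probe set. The counting software and its version are not given in the sources used here. A second deposited table held log2 values per sample and gene, whose making the labels do not describe. Set against the raw counts, the log2 values deposited by the authors equalled, within a median relative difference of at most 0.0167 in any sample, log2 of the count less a background and multiplied by a factor inverse to the arithmetic mean of the 4 references. The product of that factor and the reference mean had a coefficient of variation of 0.0685% over the samples, and the background ran from 1.02 to 10.6 counts with a median of 4.37. The table also held 18 blank rows.

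Groups were taken from the sample titles, which give leaf age, genotype, a letter and a number. The 53 probes for genes were matched by locus to a RefSeq gene table of assembly TAIR10.1, used only for names and for which genes neighbour each other; all 53 matched. The build behind the probes is not given in the sources used here, so no coordinates are printed. Loci of some of the genes named below are AT5G39610 (ANAC092), AT1G34190 (ANAC017), AT5G09330 (ANAC082), AT5G22380 (ANAC090), AT5G18270 (ANAC087), AT3G03200 (ANAC045), AT3G10480 (ANAC050) and AT3G10490 (ANAC052).

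Counts were fitted with edgeR 4.0.16 (R 4.3.3) in 1 quasi-likelihood model of all samples, with a mean per genotype and age and the title letter within age as covariate. The offset was the arithmetic mean of the 4 reference genes of the sample, since the scale has to come from outside the NAC genes. UBQ10 made up 80.6% of the reference counts (median over samples), so that mean follows UBQ10 closely. A gene was tested if its mean raw count exceeded the mean of the negative probes plus 2 SD (5.19 plus 2 times 3.71, or 12.6 counts). That left 47 genes; ANAC076 and ANAC086 were not tested. The common dispersion was 0.0892 (square root 0.299), the prior degrees of freedom 3.85 and the residual ones 222. For 14 genes below the Poisson bound the p-value was limited by a Poisson likelihood ratio test, as edgeR does. Tests were computed on the samples that bear on a contrast with the dispersions of the whole model; the largest difference in log10 p from edgeR's own function was 4.1e-08 over 4 contrasts.

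P-values were adjusted by Benjamini-Hochberg over genes for wild-type ageing, over 188 tests for targeted genes, over the 2256 pairs of line and other gene at each age and for each change with age, and over genes within age for the line labelled anac092; the threshold was an adjusted p of 0.05. A normalised count is the raw count divided by the reference mean of the sample and multiplied by the mean of the reference means; log2 values per sample are of the normalised count plus 1. Percentages of wild type have exact 95% Poisson intervals on the summed raw counts. The gene lists were compared by an exact two-sided permutation test of the mean per sample, and the mean effect of each line by a two-sided sign-flip test with 100000 resamples, both adjusted over their family. Because lines of a letter share wild-type samples, the mean effect was also set against 10000 simulations of unchanged lines, added after seeing the data, in which the mean log2 value of every sample varied with the SD between samples of a group (0.126, 0.154, 0.231 and 0.291 at the successive ages). They were repeated with a part shared by lines of the same letter and number, none of it shared with wild type, and without 10 lines of letter B. The lists were senescence-promoting, senescence-delaying, SNAC-A stress clade, ANAC092 clade, membrane-tethered, xylem and phloem NACs, and the trio of the study. The last 2 tissue lists stand for vascular cells, which a whole leaf also holds.

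The design, lists, rule for named genes and most alternatives were fixed before the data were examined. Named were, for wild-type ageing, the 10 largest rises and falls past the test at 26 d; for targeted genes, the 5 most and 5 least reduced; for line effects, per age the 5 largest rises and 5 largest falls in which both mutant samples lay beyond every wild-type sample of their letter, and the 5 lines and 5 genes with most calls; the 10 largest changes with age; and every member of a list. With 7 falls past the test at 26 d, all 7 were named.

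Alternatives were TMM scaling, DESeq2 1.42.0, no filter, a filter at a mean of 100 counts, no letter covariate, a block for letter and number, limma 3.58.1 on the authors' log2 values, a fit per age, and leaving out samples in turn. A lone sample left by this was assumed to vary like wild type and the line labelled anac092. DESeq2 was fitted per age, or to 14 d plus 1 later age, because its fit of all samples gave dispersions at their upper limit. Added after seeing the data were the geometric mean of the references with and without UBQ10, leaving out 29 libraries whose reference mean lay under 50% of the median of their age (10, 3, 15 and 1 at the successive ages, 0 of them wild type), leaving out or exchanging the 18 d labels anac053 A1 and anac055 A1, leaving out each wild-type library with the dispersions of the whole model kept, and leaving out 10 lines of letter B. Positive control probes were not used.

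Total counts per sample ran from 87608 to 687229 at 14 d, 67796 to 318251 at 18 d, 31613 to 421153 at 22 d and 116959 to 413021 at 26 d. Counting error is small for most genes at this depth, and 2 samples per line and age limit the precision. The steps were tested on simulated data with the real means and reference scale. The simulated counts varied independently between genes and samples. Real samples also shifted as a whole, and some varied together, so the shares of calls below may be too favourable. Of line effects simulated at 2-fold, 4-fold, 8-fold and 16-fold, 38%, 80%, 92% and 98% of 50 each were called in the right direction, with 4 of 8824 unchanged pairs called. Of changes with age, 32.9%, 57.3%, 82.9% and 94.7% were called at those sizes, with 12 of 6462 unchanged pairs, and of wild-type changes over 2-fold 64 of 65. Computations outside R used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6, and figures matplotlib 3.10.9.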

Results

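Transcripts of 49 NAC genes, which encode plant-specific transcription factors, were counted in leaves of Arabidopsis thaliana aged 14, 18, 22 and 26 d, together with the reference genes ACT2, ACT7, TUB2 and UBQ10. The counts came from the NanoString nCounter, which counts molecules of labelled probe bound to RNA without amplification. The samples were 434 in all. Wild type of the Columbia ecotype had 10 samples at 14 d and 8 at each later age. The line labelled anac092 had 4 samples at each age, and each of the other 48 T-DNA insertion lines, named after the NAC gene they target, had 2. Sample titles carried a letter from A to D and a number, and wild type was sampled under every letter. Of the lines with 2 samples, 17 stood under letter A, 18 under B, 8 under C and 5 under D. The labels do not say that samples of a group came from separate plants, so the p-values below measure only the spread between these samples, which may be technical. Total counts per sample ran from 31613 to 687229, with a median of 225519. Among the 345 pairs of samples of the same group, 0 held identical counts and 0 agreed within sampling noise.

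The first question was whether each line had lost the transcript it is named after. ANAC081 (also named ATAF2) in anac081 had the lowest mean log2 change. Its samples held 4 and 5 raw counts at 14 d, 1 and 3 at 22 d and 4 and 1 at 26 d, below the mean of the negative control probes (5.19), so at these ages it was not told from background. The upper 95% Poisson bounds were 0.799, 0.386 and 0.347% of wild type. At 18 d it stood at 23.5% (95% Poisson interval 20.6 to 26.8). These intervals and bounds, and those given further on, cover counting error only, and the order of the most reduced lines is limited by background. The 18 d samples of anac081 differed from each other, at 41.4 and 263 normalised counts against 793 ± 134 in wild type (SD, n = 8). Averaged over the 4 ages, the log2 change was -5.51 for ANAC041, -4.84 for ANAC019 and -4.65 for ANAC014, each lower at all 4 ages; for ANAC055 it was -4.96, with 3 of 4 ages lower. ANAC019 and ANAC055 act in responses to stress and jasmonate, and ANAC014 is a membrane-tethered member of the family. In anac019 at 26 d, 1 sample held 186 normalised ANAC019 counts and the other 8.65, against 1399.9 ± 432 in wild type (SD, n = 8). The opposite was measured in lines whose target lay far above wild type. ANAC084 averaged 5.59 log2 above wild type in the line labelled anac084 and ANAC087 5.15 in the line labelled anac087. ANAC057 (2.76), ANAC028 (1.48) and ANAC047 (1.44) completed the 5 least reduced. ANAC057 and ANAC028 lay near the negative probes in wild type at 22 and 26 d, so background limits the size of these rises. With limma on the authors' values ANAC028 changed by 3.75 and 4.44 at these ages, against 2.10 and 2.83 with edgeR.

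By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the 188 tests of 47 lines, the target was lower in 79 tests and higher in 33. It was lower at all ages in 14 lines, at some age in 12 and at none in 21. In 5 lines, those labelled anac017, anac052, anac084, anac087 and ntl9, it was higher at all 4 ages. Of the trio of lines that the study singled out, ANAC090 in anac090 changed by -0.38 at 14 d (adjusted p = 0.619), -1.73 at 18 d, -2.89 at 22 d and -2.42 at 26 d. ANAC082 in the line labelled anac082 lay between 98.9 and 114% of wild type and was called at 0 ages. ANAC017 in the line labelled anac017 lay between 231 and 289% of wild type. ANAC092 in the line labelled anac092 changed by -0.62, -0.35, -0.19 and -0.53 at the successive ages, none past the test. The positions of insertions and probes are not given in the sources used here, and a probe outside the disrupted part checks nothing, so a target at or above the wild-type level does not show that a label is wrong. The word "labelled" stands below before the name of a line, or of several in a row, whose target was lower at no age or higher at some.

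**Figure D1:**
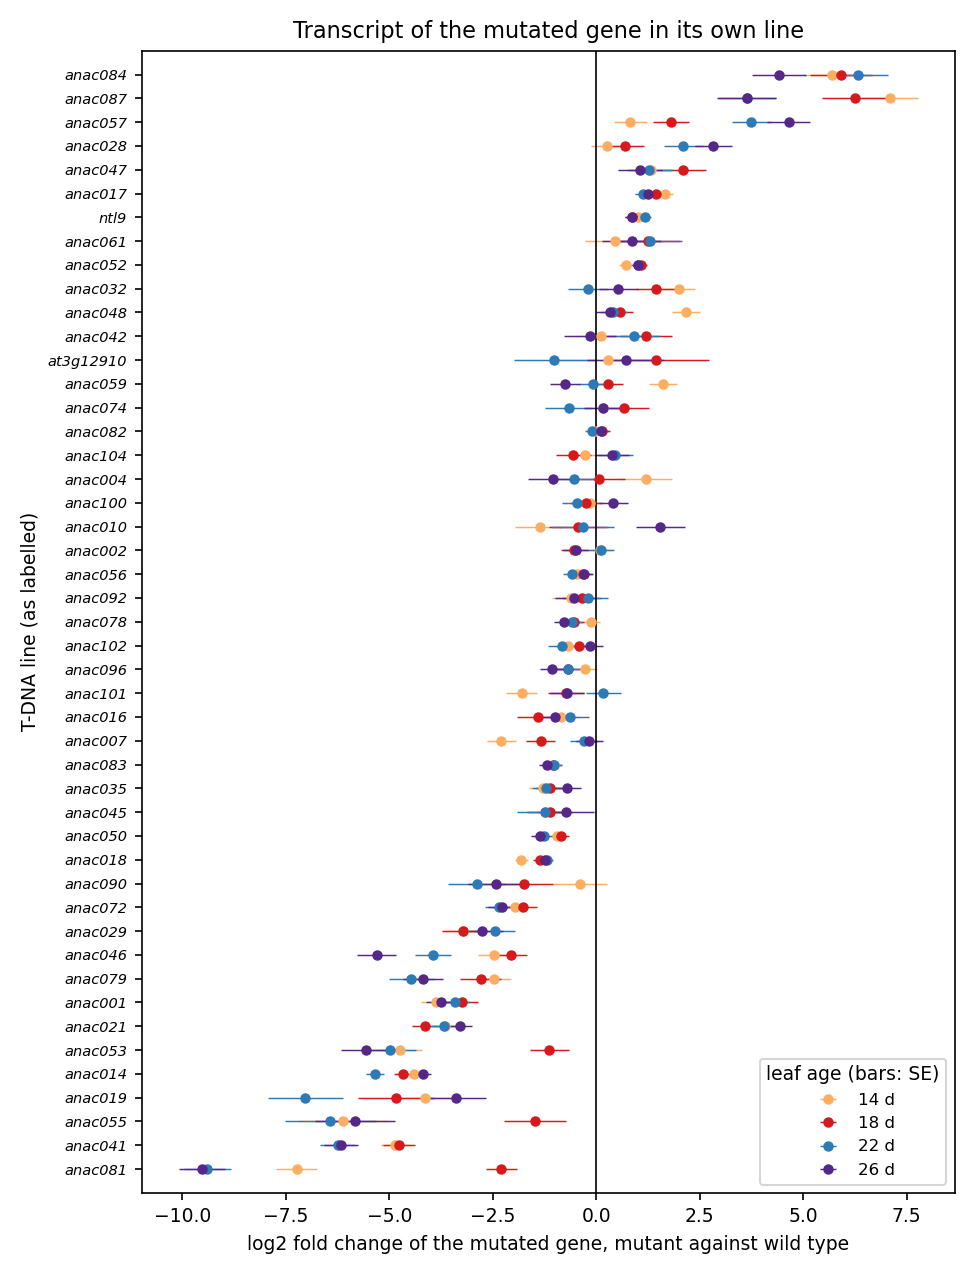
Log2 change of the targeted transcript in its own line against wild type of the same age, one point per line and age, with lines ordered by their mean over the 4 ages. ANAC081 stands at the low end with a mean of -7.12 and ANAC084 at the high end with 5.59.

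At 18 d, a pair of libraries went against their labels. The library labelled anac053 A1 held 212 normalised counts of ANAC053, 99.1% of wild type, and 3.86 of ANAC055, 2.93% of wild type. The library labelled anac055 A1 held 5.35 of ANAC053, 2.50% of wild type, and 163 of ANAC055, 124% of wild type. Wild type at 18 d had 214 ± 58.1 for ANAC053 and 132 ± 81.3 for ANAC055 (SD, n = 8). The second samples had the transcript loss of their labels, with ANAC053 at 2.07 in anac053 A2 and ANAC055 at 4.47 in anac055 A2. With the labels as given, ANAC053 in anac053 changed by -1.13 at 18 d (edgeR adjusted p = 0.030) and ANAC055 in anac055 by -1.48 (adjusted p = 0.078). With these labels ANAC055 was called with TMM (-1.78), DESeq2 (-1.63), the replicate block (-1.39) and limma on the authors' values (-3.85). With the 2 A1 labels exchanged, a setting chosen after seeing the data, ANAC055 in anac055 changed by -5.75 and passed the test. Every 18 d value of the lines labelled anac053 and anac055 below carries this doubt.

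**Figure D2:**
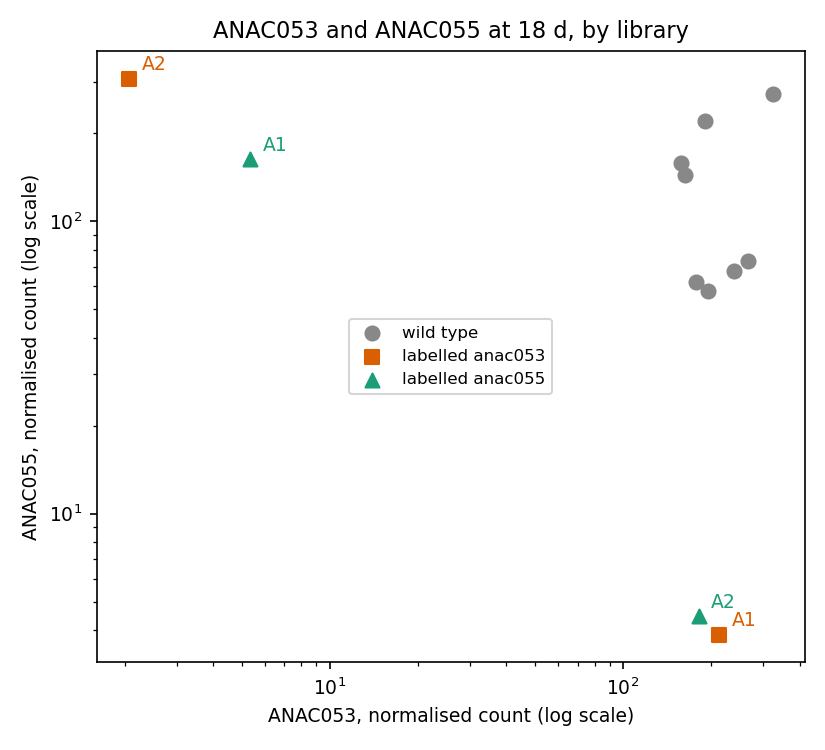
Normalised counts of ANAC053 and ANAC055 at 18 d in the 4 libraries labelled anac053 or anac055 and in the 8 wild-type libraries, on a log axis. The library labelled anac053 A1 has 3.86 counts of ANAC055 and the library labelled anac055 A1 has 5.35 of ANAC053, below every wild-type library.

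The second question was which NAC transcripts rise or fall as the wild-type leaf ages. The largest rise from 14 to 26 d was that of ANAC087, which promotes leaf senescence, from 39.2 ± 12.3 to 771 ± 278 normalised counts (SD, n = 10 and 8; log2 change 4.28, SE 0.42). ANAC055 rose from 48.1 ± 43.2 to 480 ± 121 (3.59, SE 0.39), and AT3G12910 from 14.0 ± 8.12 to 141 ± 73.8 (3.43, SE 0.51). ANAC047 rose by 2.93, ANAC019 by 2.74, ANAC059 (ORS1, a promoter of leaf senescence) by 2.69, ANAC046 by 2.54, ANAC016 by 2.41, ANAC042 by 2.13 and ANAC084 by 2.06. ANAC092, known as ORE1, a main promoter of age-dependent cell death, rose from 515 ± 301 to 1758 ± 396 (1.87, SE 0.33). The largest fall was that of ANAC045, which acts in sieve element differentiation, from 45.3 ± 8.88 to 6.15 ± 2.44 (-2.92, SE 0.25). The log2 change was -2.56 for ANAC057, -2.002 for ANAC010, -1.99 for ANAC028, -1.53 for ANAC007, -1.22 for ANAC101 and -0.78 for ANAC035 (LOV1, which delays flowering), all of which fell. The 26 d counts of ANAC045, ANAC057, ANAC010 and ANAC028 lay near the negative control probes, whose mean was 5.19 raw counts, so the size of these falls is limited by background.

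By edgeR, 39 of 47 genes were higher and 7 lower at 26 d than at 14 d, 37 and 7 at 22 d, and 12 and 6 at 18 d. ANAC050 did not pass the test at 26 d (log2 change 0.17, adjusted p = 0.115), and with TMM it was lower (-0.58, adjusted p = 2.3e-06). This split depended on the scaling, since the median change of all genes at 26 d was 1.12 log2 relative to the reference genes, 0.34 after TMM scaling (a shift of -0.78) and 0.18 with the size factors of DESeq2 (a shift of -0.94). At 22 d these shifts were -0.47 and -0.65, and at 18 d DESeq2 moved the median by -0.17. The geometric mean of the references moved it by 0.21 at 26 d and 0.15 at 22 d, and the references without UBQ10 by 0.30 and 0.21. With TMM, 24 genes were higher and 13 lower at 26 d and 21 and 9 at 22 d; with DESeq2, 20 and 15 at 26 d, 13 and 14 at 22 d, and 8 and 10 at 18 d. Relative to the median of 26 d, ANAC087 rose by 3.16. Under TMM ANAC087 changed by 3.52, ANAC055 by 2.86 and ANAC045 by -3.64. The 10 genes with the largest rise and the 7 that fell kept their direction under TMM and within each of the 4 letters. In all, 10 of the 47 genes changed sign with TMM and 14 with DESeq2. Among the genes named by size or as list members, ANAC014, ANAC017, ANAC078, ANAC082 and NTL9, called higher at 26 d with the references, lay below 14 d with TMM and DESeq2, and ANAC002, ANAC083 and ANAC102 with DESeq2 alone.

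**Figure D3:**
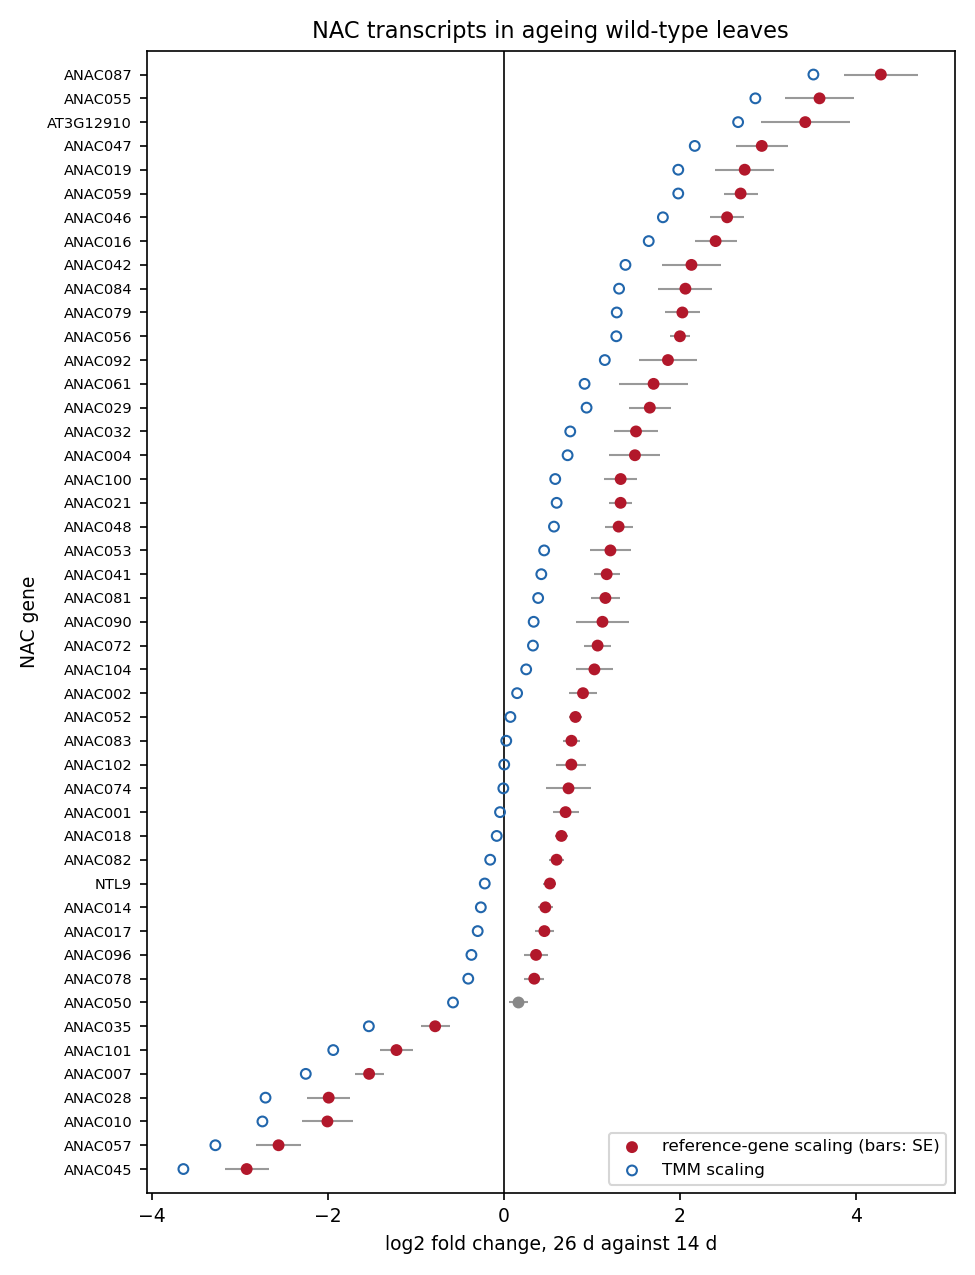
Log2 change of each tested NAC transcript in wild-type leaves at 26 d against 14 d, with reference-gene scaling (filled points, bars SE) and with TMM scaling (open points). With reference-gene scaling ANAC087 stands at the high end with 4.28 and ANAC045 at the low end with -2.92, directions that did not flip under any scaling tried.

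Gene lists fixed in advance were compared between wild type at 26 and 14 d by the mean log2 normalised count per sample. The senescence-promoting NACs lay 2.13 log2 higher at 26 d, and 13 of 13 rose, among them ANAC092 (1.87), ANAC029 (NAP, 1.66), ANAC072 (1.07, but 0.33 with TMM and 0.15, not called, with DESeq2) and ANAC002 (ATAF1, 0.90, below 14 d with DESeq2). The ANAC092 clade (ANAC059, ANAC079, ANAC092 and ANAC100) lay 2.08 higher with 4 of 4 rising, and the SNAC-A stress clade, which holds ANAC019, ANAC055 and ANAC072, 1.72 higher with 7 of 7. The senescence-delaying NACs, ANAC042 (JUB1, 2.13) and ANAC083 (VNI2, 0.77, below 14 d with DESeq2), also rose and lay 1.42 higher together. Xylem NACs lay 0.81 lower on average (log2 difference -0.81): ANAC007 (VND4), ANAC010 (SND3) and ANAC101 (VND6) fell, ANAC104 (XND1) rose by 1.03, a rise not called with TMM or DESeq2, and ANAC076 lay below the detection limit. Of the phloem NACs, ANAC045 alone was tested and fell (mean difference -2.75).

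Each of these differences had an exact two-sided permutation p of 2.3e-05 (adjusted 3.0e-05), the smallest that the 43758 arrangements can give, except the xylem list (1.1e-04, adjusted 1.3e-04); in all of them 8 of 8 samples of 26 d lay beyond every sample of 14 d. The counts adjusted over the list alone were the same as those over all genes in every list. Relative to the mean of all genes in each sample, the differences were 1.10 for the senescence-promoting, 1.05 for the ANAC092 clade, 0.69 for the SNAC-A clade, 0.39 for the delaying, -1.84 for the xylem and -3.77 for the phloem list. With TMM, 11 senescence-promoting genes rose and NTL9 fell, 5 of the SNAC-A clade, 4 of the ANAC092 clade and 1 of the delaying list rose. With DESeq2 these counts were 9 with NTL9 falling, 3, 4 and 1.

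Membrane-tethered NACs lay 0.90 higher at 26 d (exact permutation p = 2.3e-05, adjusted 3.0e-05; 6 of 6 rose, adjusted over the list alone and over all genes), but with TMM ANAC016 and ANAC053 rose while ANAC014, ANAC017, ANAC078 and NTL9 fell, and the difference was 0.14 (adjusted p = 0.080). With DESeq2 1 rose and 4 fell. Relative to the mean of all genes that list lay at -0.13 (adjusted p = 0.054); over its 4 alternatives the adjusted p ran from 2.6e-05 to 0.080. The trio of ANAC017, ANAC082 and ANAC090 lay 0.68 higher (exact permutation p = 5.3e-04, adjusted 5.3e-04; 6 of 8 samples above every sample of 14 d), and 3 of 3 rose, adjusted over the list alone and over all genes. Its direction turned with TMM, to -0.075 (adjusted p = 0.437; 0 rose and 1 fell, and 0 and 2 with DESeq2), and relative to the mean of all genes, to -0.34 (adjusted p = 0.0049); its other alternatives gave adjusted p of 5.7e-04 and 5.2e-05. The study chose the trio on these samples, so its count is not independent evidence.

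The third question was which NAC transcripts depend on which NAC gene at each age. At 14 d the largest rises stood in anac090, whose target was not called lower at this age. ANAC090 averaged 51.4 normalised counts there, against 67.0 in wild type of the same letter and 118 in all wild type. ANAC042 rose by 2.46 (SE 0.71, edgeR adjusted p = 0.043), with 380 and 220 counts in the mutant samples and 53.3 and 55.8 in wild type of the same letter. All wild type had 155 ± 91.0 of ANAC042 (SD, n = 10), so the size of this rise depends on the letter. ANAC004 rose by 2.41 (SE 0.64), where wild type averaged 27.0 in the letter and 77.5 in all. ANAC016, a membrane-tethered promoter of senescence, rose by 2.10 (SE 0.50), and ANAC001 by 1.20. In anac035, ANAC059 rose by 1.61 and ANAC048 by 1.31. ANAC082, a regulator of the response to ribosomal stress, rose by 0.96 in the line labelled anac017, with 1853 and 1373 against 819 ± 88.5 in wild type (SD, n = 10; adjusted p = 5.6e-07). ANAC056, named after its value was seen, rose by 1.14 in anac055 (adjusted p = 8.1e-06), and ANAC052 by 0.51 in anac050. The largest fall was that of ANAC050 in the line labelled anac052, with a log2 change of -4.72 and 1.22 and 55.04 normalised counts against 733 ± 50.1 (SD, n = 10). Without the second sample it was -9.19, a size set by background. In anac018, ANAC016 fell by 1.89 and ANAC046 by 1.77; ANAC102, a stress-related relative of ATAF1, fell by 1.64 in the line labelled anac010 and by 1.55 in the line labelled anac028.

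By edgeR, adjusted over the 2256 pairs of line and gene, 9 pairs were higher and 23 lower at 14 d, in 13 lines; all 23 lower pairs were in lines of letter B. Most calls fell on anac018 (6), the line labelled anac010 (4), anac090 (4), the line labelled anac028 (3) and anac046 (3), and on ANAC052 (7 lines), ANAC081 (6), ANAC102 (5), ANAC082 (3), and ANAC016 and ANAC048 (2 each). The split was 21 higher and 12 lower with DESeq2, and 2 and 1 with the references without UBQ10. With the replicate block 59 pairs were called, and 10 without the letter covariate. Without the letter covariate the calls named above ended in anac090 (ANAC042 0.95, ANAC004 0.90, ANAC016 1.12 and ANAC001 0.54), anac035 (ANAC059 0.80, ANAC048 0.58) and anac018 (ANAC016 -1.07, ANAC046 -1.27). With TMM ANAC042 (2.06) and ANAC001 (0.82) in anac090 were not called, with DESeq2 ANAC001 in anac090 (0.68) and ANAC016 (-1.26) and ANAC046 (-1.14) in anac018. In anac090, ANAC001 was also not called with limma on the authors' values (1.22) or the geometric mean of the references (1.20). Nor was ANAC042 with that mean (2.46) or without the 10 lines of letter B (2.46). Without shallow libraries ANAC016 in anac018 (-2.13), ANAC102 in the lines labelled anac010 (-1.575) and anac028 (-1.56) and ANAC004 (2.41) and ANAC042 (2.46) in anac090 were not called, and with each age fitted separately ANAC059 in anac035 (1.61) was not. Of 12 pairs named by the rule or the trio, ANAC050 in the line labelled anac052 alone was called without each library in turn: 11 were lost without the first sample of each line, when 2 pairs were called in all, and 8 without the second, when 5 were. Of the same 12, ANAC050 in the line labelled anac052 and ANAC082 in the line labelled anac017 alone stayed called with the references without UBQ10. Without wild type B1 of 14 d the count dropped from 32 to 10, with 1 lower, and ANAC046 (-1.11) and ANAC016 (-1.59) in anac018, ANAC102 in the lines labelled anac010 (-1.32) and anac028 (-1.23), and ANAC042 in anac090 (2.46) were not called. Without wild type C1 or C2 the calls in anac090 ended (ANAC042 2.42 and 2.49), and without D2 those in anac035 (ANAC059 0.77, ANAC048 1.004), while ANAC059 was 3.92 without D1; ANAC082 in the line labelled anac017 was not called without the first mutant sample (0.73).

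At 18 d, ANAC016 rose by 2.64 in anac090 (SE 0.52, adjusted p = 5.0e-04), with 465 and 607 normalised counts against 101 and 72.6 in wild type of the same letter. ANAC082 rose by 1.16 in the line labelled anac017 (adjusted p = 6.9e-08; 0.57 with TMM and 0.75 with DESeq2, both called), and ANAC052 by 0.64 in anac050 (adjusted p = 0.014). ANAC045 fell by 2.59 in anac090 (adjusted p = 0.014), from 32.0 and 27.4 to 3.69 and 5.18 counts, which lay near the negative probes, so that background limits the size of this fall (-4.14 with limma on the authors' values). ANAC050 in the line labelled anac052 had 1 raw count in each sample, below the mean of the negative probes, which allows up to 0.761% of wild type (upper 95% Poisson bound). These 5 pairs, 3 higher and 2 lower, were the calls of edgeR, and in each the 2 mutant samples lay beyond every wild-type sample of their letter. The number called was 23 without the letter covariate and 8 with the replicate block, DESeq2 or limma on the authors' values. It was 3 with the references without UBQ10. ANAC052 in anac050 was 0.34 with TMM, 0.46 with the geometric mean of the references and 0.38 with the references without UBQ10, and was called with none of these, nor was ANAC045 in anac090 without UBQ10 (-2.30) or without shallow libraries (-2.48). With each age fitted separately neither ANAC052 in anac050 nor ANAC045 in anac090 (-2.57) was called. ANAC016 in anac090 was not called without wild type C2 (2.42), ANAC045 in anac090 without C1 (-2.49), C2 (-2.71) or the second mutant sample (-2.95), and ANAC052 in anac050 without wild type A2 (0.64), the first (0.59) or the second mutant sample (0.69); without wild type C2, 3 pairs were called in all.

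At 22 d, ANAC082 rose by 0.80 in the line labelled anac017 (SE 0.17, adjusted p = 0.0035), with 1943 and 2089 normalised counts against 1067 ± 126.5 in wild type (SD, n = 8). ANAC041 fell by 1.34 in anac083 (SE 0.30, adjusted p = 0.0083), with 244 and 385 against 669 and 1081 in wild type of the same letter. ANAC050 in the line labelled anac052 had 1 raw count in each sample, again below the negative probes (upper bound 0.977% of wild type). These 3 pairs, 1 higher and 2 lower, were all that edgeR called. The split was 3 and 2 with DESeq2, 8 and 2 with the geometric mean of the references, and 9 and 2 with the references without UBQ10. Without the letter covariate 23 pairs were called, and 9 with the replicate block. ANAC082 in the line labelled anac017 was not called without the first (0.85) or the second mutant sample (0.75) or with each age fitted separately (0.80). ANAC041 in anac083 was not called without the first mutant sample (-1.07), wild type A2 (-1.03) or shallow libraries (-1.14), and was -0.87 with DESeq2. Without the second samples 7 pairs were called.

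At 26 d, ANAC010 rose by 3.15 in the line labelled anac052 (SE 0.56, adjusted p = 6.3e-05), with 28.8 and 107 normalised counts against 8.33 ± 2.21 in wild type (SD, n = 8), a level near the negative probes that limits the size of the rise (4.90 with limma on the authors' values). ANAC047 rose by 2.54 in anac090, with 923 and 3143 against 240.1 and 463 in wild type of the same letter. ANAC100, a close relative of ANAC092, rose by 1.48 in the line labelled anac017 and by 1.38 in anac079, and ANAC082 by 0.72 in the line labelled anac017 (adjusted p = 0.011), with 2286 and 1982 against 1237 ± 196 (SD, n = 8). ANAC004 fell by 2.47 in anac018, and ANAC050 in the line labelled anac052 had 1 and 5 raw counts, below the negative probes (upper bound 0.924% of wild type). ANAC010 also passed the test in the line labelled anac017 (2.63), where 1 of 2 samples lay beyond wild type (64.9 and 6.45 counts) and the value without the first sample was 0.15.

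EdgeR called 6 pairs higher and 2 lower at 26 d. The split was 1 and 2 with DESeq2, 2 and 2 with limma on the authors' values, 11 and 2 with TMM, 10 and 2 with the geometric mean of the references and 8 and 2 without UBQ10. With each age fitted separately 1 pair was called in all, against 24 without the letter covariate and 17 with the replicate block. Not called with DESeq2 or limma, in that order, were ANAC047 in anac090 (2.29 and 2.37) and ANAC100 in the line labelled anac017 (1.19 and 1.56). Nor were ANAC100 in anac079 (1.30 and 1.47) and ANAC010 in the line labelled anac017 (2.18 and 2.71). ANAC082 in the line labelled anac017 was 1.16 without UBQ10, and 0.40 with TMM and 0.47 with DESeq2, not called with either of the last, nor without the first (0.62) or second mutant sample (0.82) or wild type A2 (0.69) or B1 (0.66). ANAC100 in the line labelled anac017 lost its call without the first mutant sample (1.22) and wild type A2 (1.46), and in anac079 without the second mutant sample (1.28) and wild type A2 (1.36) and B1 (1.32). In anac079 it was also not called without the letter covariate (0.99). ANAC047 in anac090 was not called without wild type C1 (2.13), C2 (3.08) or the second mutant sample (1.40), ANAC004 in anac018 without B1 (-2.49) or B2 (-2.33), and ANAC010 in the line labelled anac052 without the second mutant sample (1.90). The number of pairs was 5 without wild type A2, B1 or the second mutant samples, and 16 without the first.

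**Figure D4:**
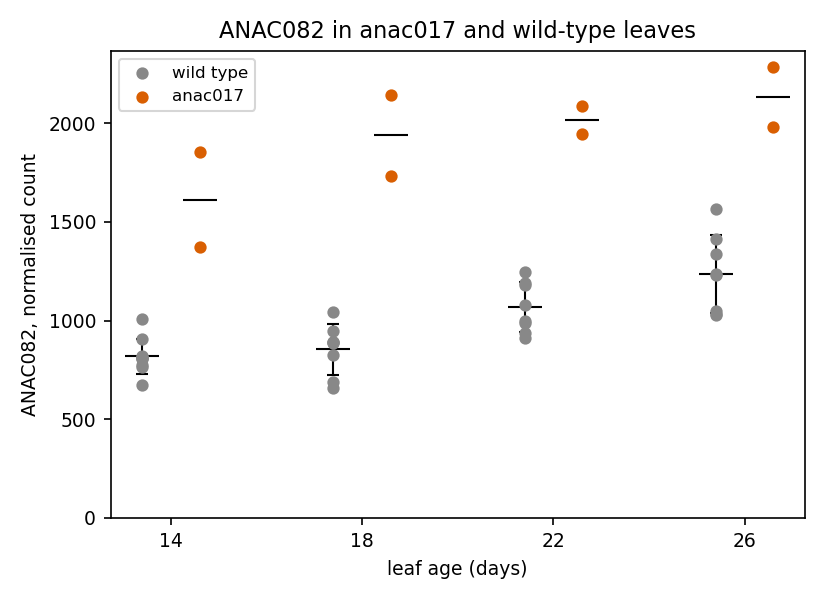
Normalised counts of ANAC082 by leaf age in the line labelled anac017 (2 libraries per age) and in wild type (10 libraries at 14 d, 8 at later ages). The libraries labelled anac017 range from 1373 to 2286 and lie above every wild-type library of their letter at each age; with TMM scaling the 26 d difference was 0.40 and did not pass the test.

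The title of the series names an inversion of regulation with age, so the change of each line's effect from 14 d to each later age was tested. ANAC081 in the line labelled anac010 changed by 1.95 from 14 to 18 d, ANAC102 by 2.16 in the same line and by 2.13 in anac046, ANAC081 in anac014 by 1.80, and ANAC052 in anac046 by 0.87. At 26 d, ANAC102 in the line labelled anac028 had changed by 1.93 and ANAC010 in the line labelled anac017 by 2.94. In the line labelled anac052, ANAC050 changed by -3.93 at 18 d, -3.64 at 22 d and -3.06 at 26 d. These last 3 values rest on sample B2 of 14 d, which held 55.04 normalised counts: without the second mutant samples they were 0.42, 1.43 and 0.37 and did not pass the test. ANAC010 in the line labelled anac017 was 0.22 without the first sample. Among the 10 largest changes, ANAC019 in the line labelled anac010 (2.91, 18 d), ANAC004 in anac090 (-2.82, 26 d), ANAC045 in anac090 (-2.72, 18 d), ANAC061 in anac101 (-2.71, 22 d) and in anac014 (2.70, 22 d) and ANAC055 in the line labelled anac017 (2.68, 26 d) did not pass it.

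By edgeR, adjusted over 2256 pairs, the change was positive in 5 pairs and negative in 1 at 18 d, negative in 1 at 22 d, and positive in 2 and negative in 1 at 26 d. A pair counted as inverted when its change passed and its effect was called with opposite sign at both ages: 0 pairs did so at any age with edgeR, and 0 with DESeq2 or limma on the authors' values. Of the changes that passed, 5 of 6 at 18 d, 0 of 1 at 22 d and 2 of 3 at 26 d had effects of opposite sign at the 2 ages, without a call at both. A call at the later age was open to the 5, 3 and 8 pairs called there. At an unadjusted p under 0.05 throughout, the counts of inverted pairs were 5, 1 and 1. The split of the 18 d changes was 2 and 1 with TMM, 4 and 10 with DESeq2, and 0 and 1 with both other scalings of the references; at 26 d it was 5 and 1, 0 and 1, and 1 and 1. With the replicate block 27, 2 and 10 changes were called at 18, 22 and 26 d. The number called moved from 6 to 1 at 18 d and from 3 to 1 at 26 d without wild type B1 of 14 d, to 17 at 18 d without B2 of 14 d, and to 16, 5 and 8 at 18, 22 and 26 d without D1 of 14 d. It was 3 at 18 d without wild type B1 of 18 d, 1 at 26 d without A1 or A4 of 14 d or A1 or B1 of 26 d, 1 at 18 and 26 d without the first mutant samples, and 1, 0 and 1 at the successive ages without the second. Of the 10 changes that passed, 6 lay in lines of letter B other than the line labelled anac052, and all 6 ended without wild type B1 of 14 d, where they ranged from 0.77 to 1.85. All 6 also ended with the geometric mean of the references (0.58 to 1.95) and without UBQ10 (0.44 to 1.85), and the 5 of 18 d without the letter covariate (0.63 to 1.65). ANAC052 in anac046 was 0.37 with TMM and 0.23 with DESeq2. The change of ANAC050 in the line labelled anac052 was not called at 22 d with DESeq2 (-4.11). With limma this change was -1.79 at 18 d and -1.98 at 22 d.

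Averaged over all genes but the target, the lines lay below wild type at 14 d (mean log2 difference -0.093, SD 0.20, n = 49 lines), 0.14 above at 18 d (SD 0.13), at -0.026 at 22 d (SD 0.18) and 0.046 above at 26 d (SD 0.19). The mean lay above 0 in 15, 43, 21 and 27 of the 49 lines. By letter, the 14 d mean was -0.078 in A, -0.25 in B, 0.20 in C and 0.0016 in D. The lower level at 14 d was thus not shared by letters C and D. The difference from 14 d was 0.23 at 18 d (sign-flip permutation p = 1e-05, the smallest that 100000 resamples can give; adjusted 3.0e-05), 0.067 at 22 d (p = 0.0773) and 0.14 at 26 d (p = 3.0e-05, adjusted 4.5e-05). Within letters it was 0.20 in A, 0.43 in B, -0.032 in C and 0.018 in D at 18 d, -0.014, 0.24, -0.19 and 0.11 at 22 d, and 0.22, 0.17, 0.0065 and -0.057 at 26 d, so the pooled direction did not hold within letter C at 18 d, A and C at 22 d or D at 26 d. With DESeq2 the 18, 22 and 26 d values were 0.020, -0.0065 and 0.033, and with TMM 0.043, 0.033 and 0.11. Both scale each sample to the NAC genes themselves, which shrinks any mean over these genes. These smaller values therefore do not decide whether the differences relative to the references hold. The sign-flip test treats the lines as independent, although those of a letter share wild-type samples. In 10000 simulations of unchanged lines with these wild-type samples shared, added after seeing the data, 95% of the differences lay between -0.15 and 0.15 at 18 d, -0.20 and 0.20 at 22 d and -0.25 and 0.25 at 26 d. The 18 d value lay outside (simulated p = 0.0033, adjusted 0.0099) and those of 22 d (p = 0.523) and 26 d (p = 0.275) within, so the 26 d difference was not larger than shared samples can give. These draws vary otherwise independently, which makes their range too narrow where lines of a letter and number vary together. With the shared part estimated from the lines added, the 18 d range was -0.16 to 0.16 (p = 0.0051, adjusted 0.015). Without 10 lines of letter B whose first library at 14 d was shallow, the 18 d difference was 0.16 (p = 0.0436, adjusted 0.131) and did not pass. Without the second mutant samples the 22 and 26 d differences were -0.026 and -0.043 (permutation p = 0.627 and 0.310). Without the first mutant samples the 22 d difference was 0.11. The 22 d difference passed the sign-flip test without wild type A3 (0.090), B2 (0.082) or D2 (0.083) of 14 d, and without A2 (0.20), C1 (0.087) or D2 (0.089) of 22 d. That test ignores the shared wild-type samples, and these values were not set against simulations of their own.

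The line labelled anac092, with 4 samples per age, was tested alone within each age. The genes with the smallest p were ANAC081 at 14 d (log2 change -0.59, SE 0.23), ANAC032 at 18 d (0.93, SE 0.38), ANAC084 at 22 d (-1.13, SE 0.51) and ANAC083 at 26 d (-0.44, SE 0.14), with edgeR adjusted p of 0.316, 0.643, 0.839 and 0.109. Of 47 genes, 0 passed at each age with edgeR, DESeq2 or limma on the authors' values, while 4, 2, 1 and 5 had an unadjusted p under 0.05. With the replicate block 5 genes passed at 14 d, and at 26 d 2 did without the letter covariate and 1 with TMM. At 26 d, 2 genes passed without sample A1 of the line labelled anac092 and 1 without wild type A1.

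The lines labelled anac017 and anac082 and the line anac090 were grouped because the study singled them out on these samples, so their counts are not independent evidence. They held 5 of the 32 called pairs at 14 d (5 higher), 3 of 5 at 18 d (2 higher and 1 lower), 1 of 3 at 22 d (1 higher) and 4 of 8 at 26 d (4 higher), as 6.12% of the lines. The calls were ANAC001, ANAC004, ANAC016, ANAC042, ANAC045 and ANAC047 in anac090 and ANAC010, ANAC082 and ANAC100 in the line labelled anac017, with 0 in the line labelled anac082. At 26 d these lines held 0 called pairs with DESeq2 or with each age fitted separately. They held 1 with limma on the authors' values and 2 with the stricter filter. At 22 d they held 2 with DESeq2, 4 with the replicate block, 6 with the geometric mean of the references, 7 without UBQ10 and 8 without the letter covariate, and 0 with separate fits. At 18 d they held 5 with DESeq2 or separate fits, 6 with the block and 14 without the letter covariate, and at 14 d 3 with TMM, the geometric mean or without shallow libraries, 1 without UBQ10 or the letter covariate and 8 with separate fits. Without wild type C1 or C2 the 14 d count was 1, without C2 of 18 d that of 18 d was 1, and without A2 of 26 d that of 26 d was 2. Without the first mutant samples the 14 d count was 0, and without the second it was 3 at 14 d, 0 at 22 d and 2 at 26 d.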

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

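All tests of explanations in this part, and the counts over other splits of the samples, were set up after the results they bear on had been seen; the changes with age and the search for far samples were planned.

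Of 54 groups of values of wild type or the line labelled anac092 searched, 4 held a sample far from the others, against about 1 in 20 by chance. Wild type B1 at 14 d had 288 normalised counts of ANAC046, the others 51.8 to 145. Wild type D2 at 14 d had 58.1 of ANAC010, the others 17.8 to 39.1. The mean log2 count of the ANAC092 clade was 4.90 in wild type D2 at 14 d and 6.66 to 7.44 in the others. The mean of the senescence-delaying NACs was 10.66 in wild type D1 at 26 d and 11.23 to 11.69 in the others.

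A tested difference between ages set apart 10 effects of lines. From 14 to 18 d these were ANAC081 (1.95) and ANAC102 (2.16) in the line labelled anac010, ANAC081 in anac014 (1.80), ANAC052 (0.87) and ANAC102 (2.13) in anac046 and ANAC050 in the line labelled anac052 (-3.93). ANAC050 in that line changed by -3.64 from 14 to 22 d and by -3.06 to 26 d. From 14 to 26 d ANAC010 changed by 2.94 in the line labelled anac017 and ANAC102 by 1.93 in the line labelled anac028. The 3 changes of ANAC050 rest on sample B2 of 14 d, with 77 raw counts, and turned to 0.42, 1.43 and 0.37 without the second mutant samples. Of the 10 changes, 6 lay in 10 lines of letter B whose first library at 14 d was shallow. These 6 were not called without the first mutant samples, nor without the second, nor without wild type B1 of 14 d. Without that wild type, ANAC081 was 1.48 and ANAC102 1.85 in the line labelled anac010, ANAC081 1.33 in anac014, ANAC052 0.77 and ANAC102 1.81 in anac046, and ANAC102 1.62 in the line labelled anac028. Without wild type B1 of 18 d, ANAC081 in the line labelled anac010 (1.89) and in anac014 (1.74) and ANAC052 in anac046 (0.76) were not called, nor was ANAC081 in anac014 without A1 (1.76) or B2 (1.82) of 18 d. ANAC102 in the line labelled anac028 was not called without wild type A1 (1.94) or A4 (1.93) of 14 d or A1 (1.85) or B1 (1.82) of 26 d. ANAC010 in the line labelled anac017 was 0.22 without the first mutant sample and was not called without wild type A1 (2.89), A3 (2.95), A4 (2.87), B1 (2.98) or B2 (2.90) of 14 d or A1 (2.90), A2 (3.16) or B1 (2.86) of 26 d.

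At 18 d the library labelled anac053 A1 lacked ANAC055 and the library labelled anac055 A1 lacked ANAC053. A mixture of the RNA of both lines in similar parts is argued against by the pattern itself, since each library would then hold both transcripts. The missing transcript stood at 2.93 and 2.50% of wild type, and the gene of its own label at 99.1% or more in both libraries. No test outside the pattern was made for a mixture. Exchanged labels stay open: outside the pattern, ANAC056, which lay above wild type in anac055 at the other ages, stood at 244% of wild type in the library labelled anac053 A1, above every wild-type library, and at 118% in the library labelled anac055 A1, within their range, as an exchange would give. This rests on 1 gene and 2 libraries, so an exchange may, as a hypothesis, be the source of the weak loss at 18 d (ANAC055 in anac055 at -5.75 when exchanged). No biological explanation was tested.

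In the line labelled anac052, ANAC050 stood at no more than 4.80% of wild type at any age, while ANAC052, with 0 genes between it and ANAC050, was higher. An exchange of the labels anac050 and anac052 stays open. ANAC052 was not reduced in any of the 8 anac050 samples (lowest 128% of wild type), but this cannot decide it, since the ANAC052 probe might read a partial transcript. ANAC050 was lower in anac050 at all 4 ages, at 42.3 to 53.1% of wild type, as the label would give. With the genes side by side, this does not decide the exchange either. An insertion that disrupts ANAC050 itself stays open: ANAC050 stood at no more than 7.51% of wild type in 8 samples, which is the pattern itself, and the insertion site is not given in the sources used here. A need of ANAC050 for ANAC052 as a transcription factor also stays open, because the ANAC052 probe read at least 169% of wild type in these samples but might read a partial transcript. An insertion in or between the neighbours could account for either, and the tables cannot tell these apart.

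At 14 d, 22 of the 23 lower calls fell on 7 lines of letter B. Wild type B1 as the whole cause stays open. In a comparison that uses no wild type, 14 of 47 genes differed in the B1 libraries between the 10 shallow lines and the other 8. Of these, 10 were lower and 4 higher in the 10 (exact permutation, adjusted). The lines were split by the depth of these same libraries (mean reference count 21634 against 39730). The comparison therefore cannot tell depth from another source and does not decide the part of wild type B1. Without wild type B1 the median log2 difference of the 22 pairs went from -1.25 (SE 0.33) to -0.85 (SE 0.36) with 0 called, because it shrank and 1 wild-type library of the letter was left; it was -0.71 (SE 0.30) with 3 called against wild type of all letters and -1.19 (SE 0.43) with 1 called without shallow libraries, but pairs chosen for being lower have a median below 0 in any case, so these values decide nothing. A batch of these 10 lines stays open, since 3 genes (ANAC052, ANAC082 and ANAC078) also differed in the B2 libraries, which are not shallow, and 0 or 1 did at the other ages. Shared targets of the mutated genes also stay open, because all 7 lines lie among these 10.

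For wild-type ageing, chance was an unlikely source of the calls. With wild type fitted alone, 1 of 100 splits of the samples of each pair of ages, the real one, gave as many genes. That is the smallest share that 100 splits can give, and the splits were not kept within letters. The real split called 16, 42 and 47 genes at 18, 22 and 26 d, and the highest other split 5, 30 and 40. For the line labelled anac092 the real count was 0 at each age, so 100 of 100 splits gave at least as many and say nothing about chance. Other splits there called up to 4, 14, 5 and 10 genes at 14, 18, 22 and 26 d; whether a structure of these samples lies behind this was not tested.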

How the results depend on the processing

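The scalings of the references, the removal of shallow or doubted libraries and of letter B lines, and the removal of wild-type libraries were chosen after seeing the data; the other settings were planned. Of 1250 alternative values for wild-type genes named by size or as list members, 1189 kept direction and call (or, for a letter alone, lay within 1 SD), 10 lost the call, 13 reversed and 38 moved (letters alone); a kept call does not mean a kept size, as for ANAC035 (-0.78, but -1.53 with TMM and -1.71 with DESeq2); of 620 for named targets 600 were unchanged in call, 3 lost and 17 gained it; of 686 for named pairs 565 were unchanged and 121 lost the call; of 518 for named changes with age 438 were unchanged, 72 lost, 5 gained and 3 reversed. Losses were most frequent without mutant replicate 1 (24) or 2 (22), and 19 arose from leaving UBQ10 out. Many of the unchanged values of wild-type genes and of pairs were fixed almost in advance. Leaving out mutant libraries hardly moves a wild-type change. The scaling did move it: of the 35 wild-type genes, 5 changed sign with TMM and 8 with DESeq2. Leaving out wild type of another letter, or other lines, hardly moves the size of a pair's effect. Depth limits ANAC045, ANAC057, ANAC010 and ANAC028 at 26 d, which lie near the negative probes, and the 29 shallow libraries. The p-values of the mean effect are of the sign-flip test, which treats lines that share wild-type samples as independent. Except where fewer samples or genes were used, the cause of a difference was not tested.

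With TMM, wild type had 21 genes higher at 22 d, and 24 higher and 13 lower at 26 d; 13 pairs were called at 26 d, 3 for the trio at 14 d, 3 changes at 18 d and 6 at 26 d, and 1 gene of the line labelled anac092 at 26 d. In wild type at 26 d, ANAC014 (-0.26), ANAC017 (-0.29), ANAC078 (-0.40), ANAC082 (-0.15) and NTL9 (-0.21) reversed, and ANAC002, ANAC083, ANAC090, ANAC102 and ANAC104 lost the call. The trio list turned to -0.075 and the difference of membrane-tethered NACs was 0.14; centred on all genes these lists were -0.34 and -0.13. With DESeq2, wild type had 10 lower at 18 d, 13 higher and 14 lower at 22 d, and 20 higher and 15 lower at 26 d. It called 8, 5 and 3 pairs at 18, 22 and 26 d (trio 5, 2 and 0), with 14, 2 and 1 changes. The difference of the mean effect from 14 d was -0.0065 at 22 d and 0.033 at 26 d (sign-flip p 0.0924). ANAC002 (-0.018), ANAC014 (-0.45), ANAC017 (-0.47), ANAC078 (-0.59), ANAC082 (-0.33), ANAC083 (-0.16), ANAC102 (-0.15) and NTL9 (-0.40) reversed in wild type at 26 d, and ANAC053, ANAC072, ANAC081, ANAC090 and ANAC104 lost the call. These settings scale to the NAC genes, most of which rose with age relative to the references. Such a scaling also shrinks the mean effect of a line, which is taken over the same genes.

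Without a filter the difference of the mean effect at 22 d from 14 d was 0.083 (sign-flip p 0.0279). The stricter filter, which tests fewer genes, left 0, 1 and 1 lower in wild type at 18, 22 and 26 d, 4 pairs at 26 d and 2 for the trio. Without the letter covariate 10, 23, 23 and 24 pairs were called at the 4 ages (trio 1, 14 and 8 at 14, 18 and 22 d), 1 and 4 changes at 18 and 22 d and 2 genes of the line labelled anac092 at 26 d. With limma on the authors' values 8 and 4 pairs were called at 18 and 26 d, 1 for the trio at 26 d and 2 changes at 22 d. With each age fitted separately the trio had 8, 5, 0 and 0 pairs at the 4 ages and 26 d had 1 pair in all; changes with age and wild-type ageing have no such fit.

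With the replicate block, 59, 8, 9 and 17 pairs were called at the 4 ages (trio 6 at 18 d and 4 at 22 d). It also called 27, 2 and 10 changes, and 5 genes of the line labelled anac092 at 14 d. The difference of the mean effect at 22 d from 14 d was 0.090 (sign-flip p 0.0155). The numbers were not used to pair the samples in the main fit. The rule set for that asked every correlation of deviations to be over 0.1. Noise over 1648 pairs can break such a rule even where samples are paired, so it does not decide the question. Over these pairs, of same-numbered samples of different groups, the mean was 0.21, from -0.77 to 0.93, and 63.8% were over 0.1. In parts of the design they deviated together, with all 15 pairs over 0.1 in letter D at 26 d (mean 0.60, lowest 0.43), 94.4% in letter C at 14 d and 93.3% in letter D at 18 d. The block ended 0 calls of named genes, added 6, and moved no other count by over 1.5 times.

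With the geometric mean of the references, 16 and 10 pairs were called at 14 and 22 d (trio 3 and 6) and 1 change at 18 d; without UBQ10, 3, 3 and 11 pairs at 14, 18 and 22 d (trio 1 at 14 d and 7 at 22 d) and 1 change at 18 d. Without shallow libraries 9 pairs were called at 14 d (trio 3) and 1 change at 18 and at 26 d. The difference of the mean effect at 22 d from 14 d was then 0.097 (sign-flip p 0.0135). Without the 10 letter B lines 9 pairs were called at 14 d and 1 change at 18 and at 26 d, and that difference was -0.00417. Within letters alone the difference of the mean effect from 14 d was -0.032 in C at 18 d and -0.057 in D at 26 d. Exchanging or leaving out the doubted 18 d labels moved no count by over 1.5 times.

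Leaving out each replicate in turn gave ranges of 8 to 13, 34 to 37 and 39 to 40 genes higher and 6 to 8, 6 to 7 and 7 to 7 lower in wild type; 70 to 80 targets lower and 32 to 34 higher; 2 to 44, 3 to 5, 2 to 7 and 5 to 16 pairs at the 4 ages (trio 0 to 5, 1 to 4, 0 to 1 and 2 to 4); 1 to 17, 0 to 5 and 1 to 8 changes; and 0 genes of the line labelled anac092 at the first 3 ages and 0 to 2 at 26 d. The change of the mean effect from the youngest age ranged from 0.18 to 0.30 at 18 d and -0.026 to 0.20 at 22 d. At 26 d it ranged from -0.043 to 0.27. For ANAC050 in the line labelled anac052, the change of the effect from the youngest age ranged from -4.67 to 0.42 at 18 d. This change ranged from -4.95 to 1.43 at 22 d and -3.52 to 0.37 at 26 d. Its upper ends were those without mutant replicate 2.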

Other observations

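The lines, genes and tests in this part were all chosen after their values had been seen.

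In anac090, the senescence-promoting NACs lay on average 0.42, 0.61, 0.62 and 0.62 log2 above wild type at 14, 18, 22 and 26 d. These means ranked 2, 2, 1 and 2 among the 49 lines and likewise among the 8 of letter C, which share wild-type samples; the median of the other lines of that letter was 0.23, 0.35, -0.16 and 0.27. In the line labelled anac017 the list mean was -0.14, 0.41, -0.19 and 0.43, and in the line labelled anac082 -0.0066, 0.48, -0.15 and 0.18. The mean over all genes but the target was 0.50, 0.38, 0.52 and 0.46 in anac090, 0.026, 0.45, -0.19 and 0.35 in the line labelled anac017 and 0.020, 0.32, -0.10 and 0.12 in the line labelled anac082, and the difference of the list from all genes was not tested.

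ANAC055 and ANAC056, with 1 gene between them, each lay above wild type in the line of the other. ANAC056 in anac055 changed by 1.14 at 14 d, 0.42 at 18 d, where 1 label is in doubt, 0.76 at 22 d and 0.76 at 26 d, and passed the test at 14 d. At 18 d, ANAC056 had 2447 normalised counts in the library labelled anac053 A1 and 2198 in anac055 A2, and 1183 in the library labelled anac055 A1, against 1004 ± 262 in wild type (SD, n = 8). ANAC055 in anac056 changed by 1.89, 2.02, 1.34 and 1.26 at the successive ages and did not pass it.

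In the line labelled anac017, ANAC016, which has 0 genes between it and ANAC017, changed by 0.65, 1.12, 0.61 and 0.16, none past the test.

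The reference genes moved apart with age in wild type. Relative to UBQ10, TUB2 lay lower at 26 than at 14 d by a log2 difference of -0.73 (exact two-sided permutation, adjusted p = 2.7e-04 over 3 genes; 7 of 8 samples below every sample of 14 d), ACT7 by -0.28 (adjusted p = 0.016) and ACT2 by -0.12 (adjusted p = 0.150).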
